A study of Mus musculus with 6 samples.

How the data were processed

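Heart RNA was measured by RNA sequencing in 6 libraries from male C57B/6J mice, 3 labelled sham and 3 labelled myocardial ischemia reperfusion injury (MIRI). Per the labels, MIRI was made by tying the left anterior descending coronary artery for 30 min, followed by 4 h of reperfusion. No times were available here for the sham libraries, so the groups could not be compared for time of sampling. Total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols; whether reads were assigned by strand was not given in the sources used here. The labels number the libraries within each group and do not state that each came from a separate animal, so the p-values measure the spread between these samples. The series also covered non-coding RNA, which was not analysed here.

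The authors deposited 1 table of FPKM values, fragments scaled to transcript length and to the mapped fragments of the library, for 54298 protein-coding transcripts with Ensembl gene identifiers and symbols. HISAT2, StringTie and SAMtools and the build mm9 are named, with no versions, per the submitters' processing notes. No count of reads was used here, and no coordinates are given. Of 21986 gene identifiers, 21810 were found in a table of current mouse gene names and 21373 carried the same symbol there. Total FPKM per library was 591805, 581331 and 560008 in sham replicates 1 to 3 and 568548, 602656 and 610369 in MIRI replicates 1 to 3. Steps among the low values gave relative depths between 0.966 and 1.04 of sham replicate 1, read from the fullest interval of ratios, which held 21 to 35 genes against a median of 3 to 5 per interval. These steps were weak, absolute depth is unknown, and no interval for counting error could be given.

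FPKM values were summed per gene, and 11311 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a mean-variance trend and 4 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Fold changes are MIRI minus sham on the log2(FPKM + 1) scale, with their standard errors (SE), and understate the change of genes with low values. Means in FPKM are given with the SD over 3 libraries. Exact values of 0 occur for genes that every cell uses, and can be failed estimates; such genes are described as listed at 0, with the value of each library. Genes with near-identical copies, among them Mt1 and Mt2, Hspa1a and Hspa1b, and the alpha and beta globin genes, can share reads, and their separate values are uncertain.

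Before the data were examined, 37 gene lists were fixed for pathways, cell types and RNA quality, and 32 of them had at least 3 members tested. Member calls were taken over all genes tested and again adjusted over the list alone. Lists were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists, and again with a correlation estimated per list. Lists share some members. The rule for genes named in the text was also fixed then. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, without genes that have only a model or clone name. It added the 2 largest called changes of each list, and all 7 AMPK subunit genes, for 76 genes in all. Other members are named where 5 or fewer moved in a direction, and these, with the kidney, liver and further genes, were chosen after their values were seen. The results of some single list members are not reported here. Single values per library were compared by an exact two-sided permutation test, which cannot go below 0.1 for 3 against 3.

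The calculation was tested on simulated data for this comparison, with 11311 genes and 200 changed genes in each of 5 simulations. It called 65.4% of genes changed 1.5-fold, 93.1% of those changed 2-fold and 97.0% of those changed 4-fold, and 5.86% of its calls were false. The simulations changed 200 genes, against 4695 called in the data, and held no shift common to all genes. These rates need not hold for the data. The set test found 20 of 20 shifted sets and 1 of 20 sets without a shift. Each simulated gene was drawn independently and the sets were random. The simulations therefore do not show how the set test behaves for lists whose members move together. The results were also computed with other pseudocounts (0.1 and 0.5), no filter, a filter at 5 FPKM, median-ratio size factors, rescaling to TPM, quantile normalization, other variance models, library weights, a replicate block, each transcript by itself, a fold threshold, fry in place of camera, and leaving out each library. Alternatives on kidney transcripts were added after the data were seen.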

Results

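The data were FPKM values of protein-coding genes in 3 sham and 3 MIRI libraries of mouse heart RNA, the latter sampled after 30 min of ischemia and 4 h of reperfusion. Total FPKM was 577715 ± 16204 in sham and 593858 ± 22255 in MIRI libraries (SD, n = 3; exact permutation p = 0.4). The 13 messenger RNAs encoded in mitochondria took 54.8% ± 1.503 of all FPKM in sham and 55.4% ± 1.44 in MIRI (SD, n = 3; exact permutation p = 0.7), and none of the 13 was called. Libraries correlated at 0.983 to 0.992 within sham, 0.970 to 0.989 within MIRI and 0.914 to 0.944 between the groups, across genes, which are not independent replicates. The first principal component held 71.9% of the variance and separated the groups. Sham replicate 3 and all 3 MIRI libraries also held transcripts typical of kidney, which are described with the genes they accompanied.

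The comparison asked which genes differed between heart libraries after ischemia and reperfusion and sham libraries. limma called 17 of 20 cytokine and chemokine genes and 19 of 24 immediate early genes higher, and 15 of 21 ion channel genes and all 9 smooth muscle and pericyte markers tested lower. Of 32 lists tested, camera called 19 at the preset correlation and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05, and fry called 19. Ptx3, a secreted pattern recognition protein, rose from 0.212 ± 0.0569 to 56.4 ± 3.43 FPKM, and the apelin receptor gene Aplnr fell from 8.09 ± 2.40 to 0.928 ± 0.351 FPKM (SD, n = 3). limma called 4695 of 11311 genes (41.5%), of which 1553 were higher (33.1%) and 3142 lower (66.9%) in MIRI. At an unadjusted p under 0.05 the number was 5866. Large changes were mostly rises, with 455 genes higher and 97 lower by at least 1 on the log2 scale. The groups did not overlap for 6311 genes, or 55.8% of those tested. Chance gives 10% for a single gene, but genes are not independent, so the share over all genes is not a test. The median log2 change of all genes was -0.11. Median-ratio size factors, which bring it near 0 by construction, moved it to 0.00. With those factors the calls were 2292 higher (52.9%) and 2038 lower (47.1%), while 63.0% of calls were lower with quantile normalization and 70.0% with rescaling to TPM. Without sham replicate 2 the lower genes numbered 2081.

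**Figure D1:**
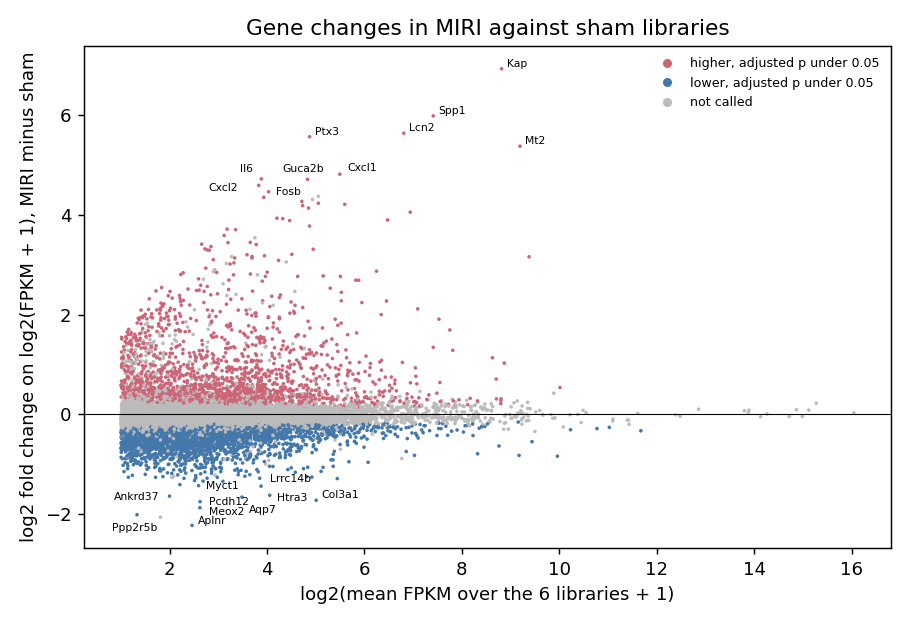
Each point is a gene; the horizontal axis is log2 of its mean FPKM over 6 libraries plus 1 and the vertical axis its log2 fold change, MIRI minus sham, on log2(FPKM + 1). Red points were called higher (1553), blue points lower (3142) and grey points not called, and the 20 genes with the largest changes under the naming rule carry their symbols.

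Among the 10 largest rises, besides Ptx3 (log2 change 5.57, SE 0.07, limma adjusted p = 1.86e-07), the metallothionein Mt2 rose from 26.6 ± 2.95 to 1142 ± 88.4 FPKM (5.38, SE 0.10). The neutrophil attractants Cxcl1 and Cxcl2 rose by 4.81 (SE 0.21) and 4.59 (SE 0.22), and Fosb, an AP-1 subunit, by 4.46 (SE 0.40). Il6 was listed at 0, 0.0295 and 0.0566 FPKM in the sham libraries and at 19.7, 40.7 and 22.1 in MIRI. The iron-binding lipocalin Lcn2 rose from 2.46 ± 0.829 to 220 ± 147 FPKM, with 50.8 in MIRI replicate 1 and 293 and 315 in replicates 2 and 3. Spp1 (osteopontin) stood at 0.121, 0.396 and 14.7 FPKM in sham and at 25.1, 508 and 468 in MIRI. Guca2b (uroguanylin) was listed at 0, 0.0483 and 3.09 in sham and at 12.6, 80.1 and 69.0 in MIRI. Kap, a kidney androgen-regulated protein, was listed at 0 in sham replicates 1 and 2 and at 193 in sham replicate 3, and at 1516, 614 and 374 in MIRI. The calls of 2 genes depended on single libraries. The limma adjusted p of Kap, 0.0280, became 0.0862 without sham replicate 1, 0.0893 without sham replicate 2, and 0.0628, 0.0690 and 0.0529 without MIRI replicates 1, 2 and 3, within a range of 0.000346 to 0.134 over its alternatives. That of Spp1, 0.0145, became 0.0514 without sham replicate 1 and 0.0529 without sham replicate 2, within a range of 0.00393 to 0.259. Over its alternatives the log2 change of Kap, 6.93, ranged from 0.405 to 9.46. The lowest value came with the kidney covariate described below, where Kap was still called.

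Among the 10 largest falls, Aplnr fell by 2.22 on the log2 scale (SE 0.21, limma adjusted p = 0.000459), the homeobox gene Meox2 by 1.87 (SE 0.16), the protocadherin Pcdh12 by 1.75 (SE 0.13) and Myct1 by 1.43 (SE 0.15). The fibrillar collagen Col3a1 fell from 48.5 ± 10.7 to 13.9 ± 1.97 FPKM and the secreted protease Htra3 from 24.1 ± 1.65 to 7.18 ± 0.679 FPKM. The aquaglyceroporin Aqp7 fell from 16.0 ± 1.89 to 4.39 ± 0.408 FPKM, Ankrd37 from 5.06 ± 1.505 to 0.934 ± 0.408, and Lrrc14b from 20.4 ± 0.628 to 7.03 ± 1.69. Ppp2r5b, a regulatory subunit of protein phosphatase 2A, stood at 2.66, 3.14 and 3.30 FPKM in sham and was listed at 0 in all 3 MIRI libraries.

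Inflammatory genes rose as a group. Of 20 cytokines and chemokines tested, 17 rose and 1, Cxcl12, fell by 0.56 (18 adjusted over the list alone, median 2.40, camera adjusted p = 8.78e-15). With an estimated correlation the camera adjusted p = 0.123. All 15 NF-kB feedback genes tested rose (15 adjusted over the list alone, median 1.34, camera adjusted p = 9.50e-13, adjusted p = 0.240 with an estimated correlation). Among them the endothelial selectins Selp and Sele rose from 0.266 ± 0.0840 to 12.2 ± 2.33 and from 0.575 ± 0.199 to 9.51 ± 2.49 FPKM. Of 16 IL-6 and STAT3 genes, 15 rose (15 adjusted over the list alone, median 1.90, camera adjusted p = 4.18e-16, adjusted p = 0.123 with an estimated correlation), with Lcn2 and the feedback inhibitor Socs3 (4.14, SE 0.22) in front. Lcn2 is also a marker of injured kidney tubule and was highest in the libraries richest in such markers, MIRI replicates 2 and 3. Of 20 interferon response genes, 11 rose, led by Ifit1 (1.97, SE 0.12) and Oasl1 (1.96, SE 0.07), and 1 fell. Adjusted over the list alone 13 were called, 12 higher and 1 lower (median 0.51, camera adjusted p = 3.12e-07, adjusted p = 0.273 with an estimated correlation). In no called list of this comparison did the set test hold with an estimated correlation. The glucocorticoid response list lost its call although its estimated correlation, 0.00325, lay below the preset 0.01. Its unadjusted camera p went from 5.14e-06 to 0.00916, so the lost calls do not measure correlation between members alone. For this list a higher correlation is not the reason. A p-value with an estimated correlation therefore does not by itself show that the members of a list move together.

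Markers of neutrophils rose and those of monocytes and macrophages were divided. All 12 neutrophil markers tested rose (12 adjusted over the list alone), with S100a9 going from 12.3 ± 1.16 to 231 ± 85.5 FPKM and Retnlg from 1.30 ± 0.0610 to 36.7 ± 17.1 FPKM. Their mean log2(FPKM + 1) was 0.95 ± 0.06 in sham and 3.59 ± 0.32 in MIRI (SD, n = 3; exact permutation p = 0.1, the smallest possible). The camera adjusted p was 2.73e-13 for the neutrophil list, and adjusted p = 0.124 with an estimated correlation. Of 15 monocyte and macrophage markers, 5 rose, namely Ly6c2 (0.99, SE 0.14), Itgam (0.93, SE 0.10), Msr1, Ccr2 and Fcgr1, and Csf1r and C1qa fell (8 adjusted over the list alone, median 0.14, camera adjusted p = 0.0338). The camera adjusted p = 0.605 with an estimated correlation, and it was 0.172, 0.0687 and 0.0768 without sham replicate 3, MIRI replicate 2 and MIRI replicate 3, 0.0516 with median-ratio factors and 0.215 with no filter, within a range of 4.60e-05 to 0.915. No lymphocyte marker reached the filter.

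Of 24 immediate early genes tested, 19 rose and none fell (20 adjusted over the list alone, median 1.45, camera adjusted p = 2.23e-12, adjusted p = 0.302 with an estimated correlation). Atf3, a stress-induced transcription factor, went from 2.97 ± 0.425 to 53.6 ± 9.44 FPKM. Of 16 heat shock genes, 8 rose and Chordc1 fell by 0.42 (9 adjusted over the list alone, median 0.26, camera adjusted p = 0.00147, adjusted p = 0.302 with an estimated correlation). The inducible chaperones Hspa1a and Hspa1b rose by 2.56 (SE 0.15) and 1.88 (SE 0.23). Of 18 genes of the unfolded protein and integrated stress response, 8 rose, among them Ppp1r15a (1.16, SE 0.14) and Xbp1 (0.94, SE 0.11), and Trib3 fell by 0.64. Adjusted over the list alone 11 were called (median 0.22, camera adjusted p = 0.000632, adjusted p = 0.403 with an estimated correlation). Of 19 oxidative stress and NRF2 genes, 12 rose (12 adjusted over the list alone, median 0.85, camera adjusted p = 1.65e-08, adjusted p = 0.123 with an estimated correlation), and Hmox1, heme oxygenase 1, went from 4.67 ± 0.762 to 55.05 ± 5.17 FPKM.

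Hypoxia, cell death and autophagy genes moved in both directions. Of 18 hypoxia and HIF targets, 5 rose (Ddit4, 1.30, SE 0.16; Ndrg1, Slc2a1, Hif1a and Adm) and 6 fell, led by Ankrd37. Adjusted over the list alone 12 were called; the median was -0.11, or 0.02 with median-ratio factors, while the mean was 0.06 and camera pointed up (camera adjusted p = 0.401). Of 27 genes of programmed cell death, 12 rose, with Ptgs2 at 2.39 (SE 0.18) and the TWEAK receptor gene Tnfrsf12a at 2.28 (SE 0.09), and Bcl2, Bbc3 and Casp9 were among those that fell. The list had 17 calls adjusted over the list alone (median 0.30, camera adjusted p = 0.000236, adjusted p = 0.155 with an estimated correlation). Of 22 autophagy and mitophagy genes, the lysosomal genes Ctsl (1.08, SE 0.21) and Lamp2 (0.47, SE 0.06) rose, and Atg5, Atg12, Ulk1, Ulk2 and Bnip3l fell. Adjusted over the list alone 6 were called; the median was -0.01, or 0.11 with median-ratio factors, and camera pointed up (camera adjusted p = 0.556).

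Glucocorticoid response genes rose in 8 of 12 cases, with Cdkn1a at 2.77 (SE 0.20) and the lipoprotein lipase inhibitor Angptl4 at 2.03 (SE 0.16), and Sult1a1 fell (9 adjusted over the list alone, median 1.05, camera adjusted p = 1.65e-05, adjusted p = 0.123 with an estimated correlation). Of 15 circadian clock genes, Cry1 and Cry2 rose and 6 fell, with Nr1d1 going from 41.5 ± 3.55 to 17.1 ± 3.88 FPKM and Dbp from 46.2 ± 3.58 to 20.9 ± 5.31 FPKM (8 adjusted over the list alone, median -0.26, camera adjusted p = 0.725). Of 3 cell cycle genes above the filter, Mki67, a proliferation marker, fell from 1.499 ± 0.291 to 0.663 ± 0.0542 FPKM (1 adjusted over the list alone, median -0.18, camera adjusted p = 0.312). With no filter 8 members of this list were called and the camera adjusted p was 0.00477, and fry gave an adjusted p of 0.0109, within a range of 0.00477 to 0.605.

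**Figure D2:**
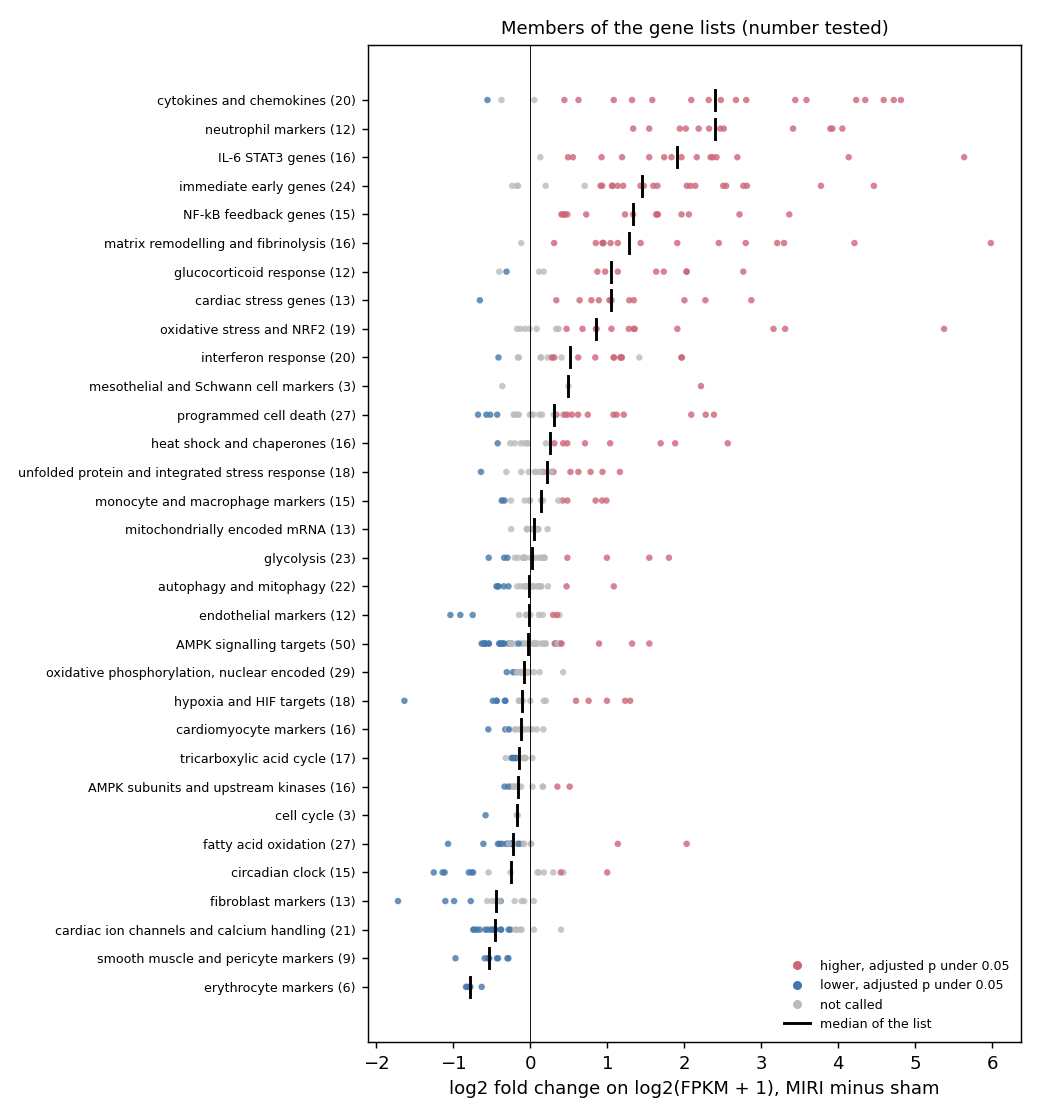
Each point is a tested member of a gene list; the horizontal axis is its log2 fold change on log2(FPKM + 1), MIRI minus sham, and the number tested stands beside each list. Black bars are medians, from -0.79 for erythrocyte markers to 2.40 for cytokines and chemokines; red members were called higher, blue lower and grey not called.

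The series title names signalling by AMP-activated protein kinase (AMPK), a sensor of cellular energy made of alpha, beta and gamma subunits. Of its 7 subunit genes, 6 were tested and 1 fell. Prkaa1 (ENSMUSG00000050697), which encodes the alpha 1 subunit, went from 6.02 ± 0.451 to 4.58 ± 0.492 FPKM (log2 change -0.33, SE 0.09, limma adjusted p = 0.0232). Prkaa2, the gene of the alpha 2 subunit, stood at 26.7 ± 1.88 and 22.3 ± 2.70 FPKM (-0.25, SE 0.10, limma adjusted p = 0.0756). The log2 changes were -0.21 (SE 0.07) for Prkab1, 0.03 (SE 0.08) for Prkab2, -0.17 (SE 0.06) for Prkag1 and -0.25 (SE 0.09) for Prkag2, with limma adjusted p = 0.0553, 0.805, 0.0648 and 0.0647. Prkag3 was under the filter, at 0.366 ± 0.133 FPKM in sham and 0.469 ± 0.149 in MIRI. The call of Prkaa1 ended with median-ratio factors (limma adjusted p = 0.0534) and without sham replicate 1 (0.0702), sham replicate 2 (0.0834), MIRI replicate 2 (0.0663) or MIRI replicate 3 (0.0671), within a range of 0.00964 to 0.286. Without MIRI replicate 1 Prkaa2 and Prkag2 were called lower (limma adjusted p = 0.0194 and 0.0149, ranges 0.0194 to 0.623 and 0.0149 to 0.515), and without sham replicate 2 Prkab1 was (limma adjusted p = 0.0443, range 0.0443 to 0.373).

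Of 16 AMPK subunits and upstream genes tested, Sesn2 and Cab39 rose and Prkaa1 and Stradb fell (4 adjusted over the list alone, median -0.16, or -0.04 with median-ratio factors, camera adjusted p = 0.725). Sesn2, a stress-induced sestrin, went from 0.818 ± 0.0471 to 1.59 ± 0.180 FPKM, and Cab39, a partner of the kinase LKB1, from 34.5 ± 0.587 to 44.4 ± 3.05 FPKM. This list had 3 genes higher and 0 lower with median-ratio factors, 3 higher and 5 lower with quantile normalization, 2 calls without sham replicate 1, 8 without MIRI replicate 1 and 0 with the kidney covariate described below. Of 50 AMPK signalling targets, 7 rose and 17 fell (26 adjusted over the list alone, camera adjusted p = 0.725). Their median was -0.03, or 0.09 with median-ratio factors, their mean -0.02, and camera pointed up. Pfkfb3, which makes the activator of phosphofructokinase, went from 5.23 ± 0.712 to 17.1 ± 1.23 FPKM, and the insulin receptor substrate gene Irs2 from 4.12 ± 0.237 to 12.2 ± 4.47 FPKM. With median-ratio factors 12 targets were higher and 10 lower, and with MIRI replicate 1 as the only MIRI library 8 were higher and 2 lower. With the kidney covariate 1 was higher and 6 lower. The targets had 15 calls without each of sham replicates 1, 2 and 3 and MIRI replicate 3.

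**Figure D3:**
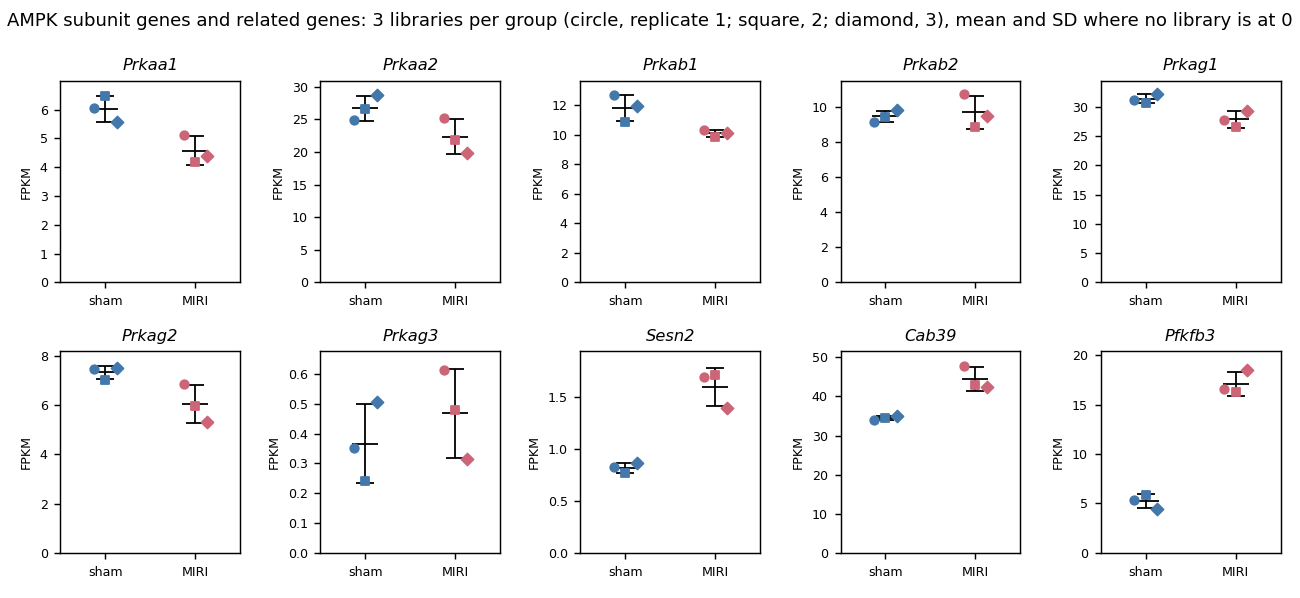
FPKM of the 7 AMPK subunit genes and of Sesn2, Cab39 and Pfkfb3 in 3 sham (blue) and 3 MIRI (red) libraries; points are libraries and bars are the mean and SD. Prkaa1 was called lower and Sesn2, Cab39 and Pfkfb3 higher, while the other tested subunit genes were not called.

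Of 27 fatty acid oxidation genes, 14 fell and 2 rose (18 adjusted over the list alone, median -0.23, or -0.10 with median-ratio factors, camera adjusted p = 0.0330, adjusted p = 0.605 with an estimated correlation). The 2 that rose do not oxidise fatty acids themselves: Angptl4, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, which went from 245 ± 21.2 to 544 ± 84.7 FPKM. Without sham replicate 3, MIRI replicate 1 or MIRI replicate 2 the camera adjusted p was 0.0637, 0.114 and 0.0556, within a range of 0.00108 to 0.605, and 9 members were called without sham replicate 3 or without MIRI replicate 2. With median-ratio factors 6 members were called and the camera adjusted p was 0.165. Of 23 glycolysis genes, Slc16a3 (a lactate transporter, 1.80, SE 0.37), Pfkfb3, Slc2a1 and Pfkp rose and Slc2a4, Pfkl and Pfkfb2 fell (7 adjusted over the list alone, median 0.03, or 0.16 with median-ratio factors, camera adjusted p = 0.103, 0.0308 with median-ratio factors and 0.0498 without sham replicate 3, within a range of 0.0308 to 0.687).

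Of 17 tricarboxylic acid cycle genes, Ogdh (-0.25, SE 0.07), Dlat (-0.23, SE 0.07), Cs, Idh3a and Mdh2 fell (3 adjusted over the list alone, median -0.14, or -0.01 with median-ratio factors, camera adjusted p = 0.103). The list had 1 call without sham replicate 1 and 0 without sham replicate 2, sham replicate 3, MIRI replicate 2 or MIRI replicate 3. With quantile normalization it had 12 calls and a camera adjusted p of 0.00249, within a range of 0.00249 to 0.778. Of 29 nuclear genes of oxidative phosphorylation, Cox7a1 (-0.31, SE 0.10), Ndufa10 (-0.22, SE 0.06) and Sdha fell, and 0 were called adjusted over the list alone. The median was -0.08, or 0.05 with median-ratio factors (camera adjusted p = 0.401, and 0.0352 without MIRI replicate 3, within a range of 0.00532 to 0.997). Leaving out any library except MIRI replicate 1 left 0 or 1 calls in this list, while quantile normalization gave 13 and median-ratio factors 0. The limma adjusted p of Ogdh, Dlat, Cox7a1 and Ndufa10 was 0.0248, 0.0434, 0.0396 and 0.0234, and with median-ratio factors it was 0.173, 0.270, 0.259 and 0.223. Ogdh was not called without sham replicates 1, 2 or 3 or MIRI replicates 2 or 3 (limma adjusted p = 0.0614, 0.0506, 0.0800, 0.0853 and 0.0631, range 0.0116 to 0.276), nor Dlat without sham replicates 2 or 3 or MIRI replicates 2 or 3 (limma adjusted p = 0.113, 0.129, 0.106 and 0.112, range 0.0101 to 0.336). Cox7a1 was not called without sham replicates 1, 2 or 3 or MIRI replicates 1 or 2 (limma adjusted p = 0.116, 0.104, 0.0646, 0.0795 and 0.115, range 0.00394 to 0.443), nor Ndufa10 without sham replicates 2 or 3 or MIRI replicates 2 or 3 (limma adjusted p = 0.0584, 0.0774, 0.0716 and 0.0611, range 0.0110 to 0.223). Without MIRI replicate 1 the camera adjusted p of the mitochondrially encoded messenger RNAs was 0.0306 (upward, 1 member called), against 0.176 with all libraries and a range of 0.00730 to 0.885.

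Ion channel and calcium handling genes fell and cardiac stress genes rose. Of 21 ion channel and calcium handling genes, 15 fell and none rose (15 adjusted over the list alone, median -0.46, camera adjusted p = 0.000316, adjusted p = 0.403 with an estimated correlation). The gap junction gene Gja1 went from 144 ± 9.08 to 85.9 ± 6.53 FPKM and Kcnj11, a subunit of the ATP-sensitive potassium channel, from 27.0 ± 2.18 to 15.9 ± 1.25 FPKM. Of 13 cardiac stress genes, 11 rose, with Cyr61 at 2.87 (SE 0.11) and Ctgf at 2.27 (SE 0.07), and Acta1 fell by 0.66 (13 adjusted over the list alone, median 1.05, camera adjusted p = 1.70e-09, adjusted p = 0.123 with an estimated correlation). Of 16 cardiomyocyte markers, Tcap (-0.55, SE 0.08), Myh6 (-0.33, SE 0.07) and Ckm fell (3 adjusted over the list alone, median -0.12, or 0.01 with median-ratio factors, camera adjusted p = 0.365), and 6 were called without MIRI replicate 3. The call of Myh6 ended with median-ratio factors (limma adjusted p = 0.0868, range 0.00824 to 0.144).

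Of 16 genes of matrix remodelling and fibrinolysis, 15 rose (15 adjusted over the list alone, median 1.29, camera adjusted p = 9.20e-12, adjusted p = 0.123 with an estimated correlation), led by Spp1 and by Thbs1, which went from 3.94 ± 0.502 to 90.8 ± 14.3 FPKM. Of 13 fibroblast markers, the collagen genes Col3a1, Col1a1 (-1.10, SE 0.13), Col5a1 and Col1a2 and the transcription factor gene Tcf21 fell (9 adjusted over the list alone, median -0.44, camera adjusted p = 0.0222, adjusted p = 0.605 with an estimated correlation). Without MIRI replicate 1 the camera adjusted p of this list was 0.0936, within a range of 0.00205 to 0.605. All 9 smooth muscle and pericyte markers tested fell, including Kcnj8 (-0.97, SE 0.10) and Notch3 (-0.59, SE 0.07), and 9 were called adjusted over the list alone (median -0.54, camera adjusted p = 0.00175, adjusted p = 0.240 with an estimated correlation). Of 12 endothelial markers, Egfl7 (-1.04, SE 0.11), Kdr (-0.91, SE 0.11) and Tek fell and Esam and Robo4 rose (5 adjusted over the list alone, camera adjusted p = 0.725). The endothelial median was -0.02, or 0.10 with median-ratio factors, the mean -0.14, and camera pointed up.

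All 6 erythrocyte markers tested fell (6 adjusted over the list alone, median -0.79, camera adjusted p = 0.0385, adjusted p = 0.605 with an estimated correlation), with the globin genes Hbb-bs at -0.84 (SE 0.20) and Hba-a1 at -0.82 (SE 0.20). Without MIRI replicate 1 or MIRI replicate 3 the camera adjusted p was 0.117 and 0.0508, within a range of 0.000257 to 0.605. Of 3 mesothelial and Schwann cell markers, Krt8 rose by 2.22 (SE 0.35), and 3 were called adjusted over the list alone (median 0.49, camera adjusted p = 0.257); 2 were called without MIRI replicate 1 or MIRI replicate 2. Krt8 stood at 0.0360, 0.0549 and 0.714 FPKM in sham and at 2.35, 6.10 and 6.90 in MIRI, higher in the libraries with kidney transcripts. Of the adipocyte markers 2 were tested and 0 called, with 0 adjusted over the list alone, and no atrial, fast skeletal muscle or lung marker reached the filter.

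Kidney transcripts were present in sham replicate 3 and in all 3 MIRI libraries. The mean of 28 kidney tubule markers was 0.0275, 0.0300 and 11.5 FPKM in sham replicates 1 to 3 and 83.6, 30.3 and 18.1 FPKM in MIRI replicates 1 to 3. For the 27 markers present in sham replicate 3, ratios to that library were also taken. Their median was 6.68 in MIRI replicate 1, 1.58 in MIRI replicate 2 and 0.709 in MIRI replicate 3. By this median MIRI replicate 3 was below sham replicate 3, although its mean was higher. The mean of 10 markers of injured kidney tubule was 0.324, 0.459 and 2.04 FPKM in sham and 7.81, 112 and 97.1 FPKM in MIRI. Umod, the tubule gene of uromodulin, was listed at 0.0126, 0 and 12.3 FPKM in sham and at 59.7, 49.0 and 30.7 in MIRI, and the injury marker Havcr1 at 0, 0 and 0.143 in sham and 0.140, 26.5 and 25.2 in MIRI. Lcn2 and Spp1 belong to the injury markers as well as to the IL-6 and matrix lists, and Krt8 followed the same pattern. The log2 of the mean FPKM of the 28 tubule markers, highest in MIRI replicate 1, was then used as a covariate. It does not follow the injury markers, which were highest in MIRI replicates 2 and 3. A call that it leaves in place therefore does not argue against RNA of injured kidney. Within the groups, the covariate differed mostly between sham replicate 3 (mean of 11.5 FPKM) and sham replicates 1 and 2 (0.0275 and 0.0300 FPKM). The adjusted values therefore rest largely on 1 sham library. A lost call does not separate kidney RNA from other differences of that library or from the larger SE. With this covariate, 691 genes were higher and 712 lower, and limma no longer called 18 of the named genes. The SE of all 18 rose, by 1.29 to 1.71 times, with a covariate that was itself higher in MIRI. Among these 18, 4 folds grew while 14 shrank, to 55.4% at the least. Kap, which kept its call, went from a log2 change of 6.93 to 0.405. For the 18 genes, the log2 changes before and after, with SE, were 5.98 (1.40) and 3.73 (2.10) for Spp1, 4.71 (0.80) and 3.50 (1.22) for Guca2b, 0.51 (0.09) and 0.44 (0.16) for Sesn2, 0.35 (0.07) and 0.29 (0.11) for Cab39, 1.32 (0.21) and 1.27 (0.36) for Irs2, and 1.08 (0.21) and 1.24 (0.35) for Ctsl. They were 0.47 (0.06) and 0.41 (0.10) for Lamp2, 1.80 (0.37) and 1.73 (0.63) for Slc16a3, -0.25 (0.07) and -0.36 (0.10) for Ogdh, -0.23 (0.07) and -0.36 (0.10) for Dlat, -0.31 (0.10) and -0.17 (0.15) for Cox7a1, and -0.22 (0.06) and -0.33 (0.09) for Ndufa10. They were -0.58 (0.11) and -0.32 (0.15) for Mki67, -0.55 (0.08) and -0.47 (0.14) for Tcap, -0.84 (0.20) and -0.72 (0.34) for Hbb-bs, -0.82 (0.20) and -0.73 (0.33) for Hba-a1, 2.22 (0.35) and 1.84 (0.57) for Krt8, and -0.33 (0.09) and -0.25 (0.15) for Prkaa1. Called list members went from 298 to 172 and the count changed more than 1.5 times in 21 lists, with the AMPK signalling targets from 24 to 7, the immediate early genes from 19 to 11, the erythrocyte markers from 6 to 0, the smooth muscle and pericyte markers from 9 to 3 and the fibroblast markers from 5 to 3. Cytokines and chemokines went from 18 to 17 calls (medians 2.40 and 2.40) and NF-kB feedback genes from 15 to 14 (1.34 and 1.48). IL-6 and STAT3 genes went from 15 to 13 calls (medians 1.90 and 2.11) and neutrophil markers from 12 to 11 (2.39 and 2.36). The set calls of the erythrocyte and fibroblast markers ended (camera adjusted p = 0.139, range 0.000257 to 0.605, and camera adjusted p = 0.431, range 0.00205 to 0.605). The erythrocyte median went from -0.79 to -0.71 while the median SE of the members rose from 0.20 to 0.33, and the fibroblast median shrank from -0.44 to -0.17 with median SE of 0.14 and 0.20. The smooth muscle and pericyte median went from -0.54 to -0.48 and its median SE from 0.09 to 0.13, and its set call held (camera adjusted p = 0.00418, range 0.000504 to 0.240). With MIRI replicate 1 as the only MIRI library, 1286 genes were higher and 1140 lower, and with 190 genes of the kidney pattern left out, 1497 were higher and 3263 lower.

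**Figure D4:**
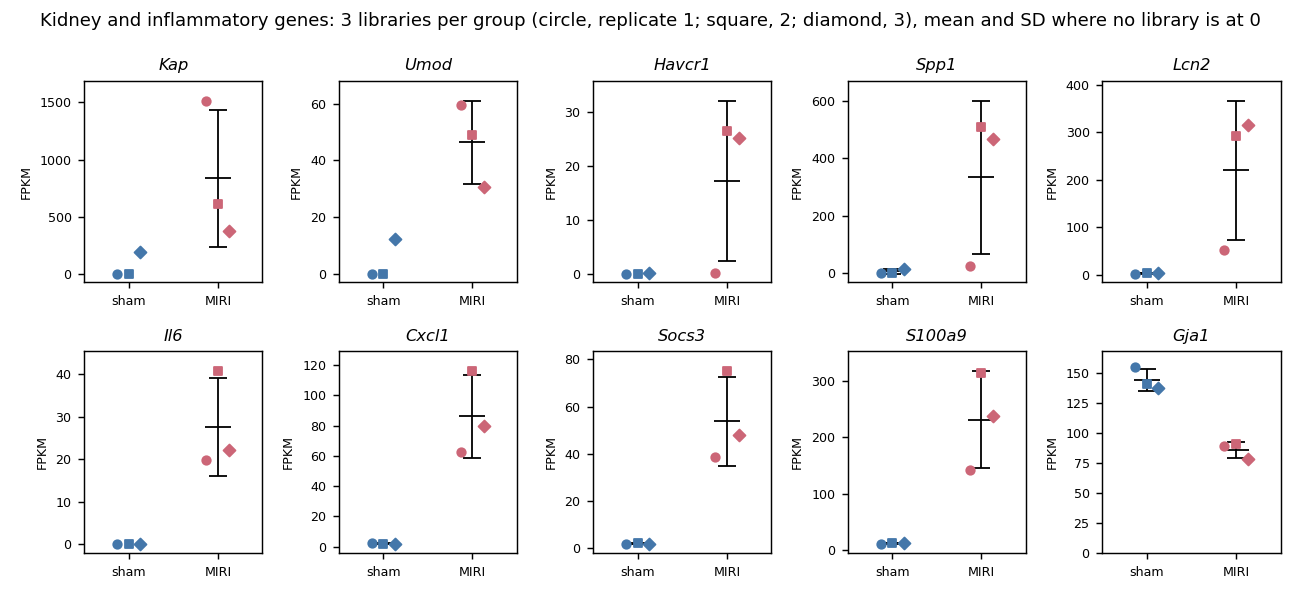
FPKM of the kidney genes Kap, Umod and Havcr1 and of inflammatory and cardiac genes in 3 sham (blue) and 3 MIRI (red) libraries; points are libraries, and bars are the mean and SD where no library is listed at 0. Kap and Umod were present in sham replicate 3, Havcr1 was high only in MIRI replicates 2 and 3 among these 6 libraries, and Il6, Cxcl1, Socs3 and S100a9 were higher in all 3 MIRI libraries.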

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

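Alternatives on kidney transcripts were chosen after the data were seen; all others were planned. No call was reversed in any alternative. Of 1503 alternative values for the named genes, 1420 kept their side of the threshold, 76 lost the call and 7 gained it. Of 669 for single set tests, 616 kept their side, 40 lost the call and 13 gained it. An uncalled value that changed direction counts as kept, as for Prkab2, with log2 changes from -0.0639 to 0.166. Of 659 counts of called list members, 573 stayed within 1.5 times the main count and 86 did not. The 1553 higher genes became 955 with a filter at 5 FPKM, which tests fewer genes, 455 at an absolute log2 change of at least 1, and 691 with the kidney covariate. The 3142 lower genes became 1531, 97 and 712 under these settings, 2038 with median-ratio size factors, 1140 with MIRI replicate 1 as the only MIRI library, which is assumed to vary like the sham libraries, and 1891 when each of 15443 transcripts was tested by itself. Leaving out each library gave 1148 to 1522 higher genes and 2081 (without sham replicate 2) to 3550 (without MIRI replicate 1) lower genes, 254 to 299 called list members and 17 to 19 called lists. Called list members, 298, became 172 with the kidney covariate. Called lists, 19, became 0 with an estimated correlation, where the lowest adjusted p was 0.123. Apart from the fewer genes or samples tested, the cause was not tested. With robust variance no set test was run, since camera has no such option. Deviations of samples with the same replicate number correlated at -0.26, 0.09 and -0.44, and not every sample correlated best with its own number. These values give no evidence that the numbers pair the samples. They cannot exclude a pairing, since kidney content also differed within groups, and sham replicate 3 correlated at 0.41 with MIRI replicate 1. A replicate block gave 1238 higher and 2174 lower genes. Without read counts, the depth behind a single low value is unknown.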

Other observations

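All lists in this part and all tests were chosen after the data were seen, except the splits of the samples and the test that scales the kidney excess of sham replicate 3. The scaling settings were planned, but the test of the share of lower calls was not. Genes with symbols starting in Zfp, most of which encode zinc finger proteins, fell in 146 of 267 cases and rose in 8 (median log2 change -0.39, or -0.29 with median-ratio factors; camera p = 1.39e-07, and p = 0.287 with an estimated correlation). Of 24 ribosomal protein genes, 6 rose and none fell (median 0.18, or 0.31 with median-ratio factors; camera p = 2.79e-06, and p = 0.257 with an estimated correlation). Of 18 Notch pathway genes, 10 fell, among them the effectors Heyl (-1.28), Hey1 (-1.17) and Hey2 (-0.75), and Notch1, Notch2 and Maml1 rose (median -0.37; camera p = 0.0425, and p = 0.307 with an estimated correlation). This Notch list replaced a first version, tested before it, that held genes already seen to fall.

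Sham replicate 3 held kidney transcripts that sham replicates 1 and 2 lacked, with Kap at 193 FPKM against 0 and 0, and none of the 28 tubule markers reached 1 FPKM in sham replicates 1 or 2. None of these markers belongs to the lists fixed for heart. Of the 27 markers present there, 85.2% stood within 2-fold of 1 ratio, 6.68, between MIRI replicate 1 and sham replicate 3, consistent with kidney RNA mixed into both libraries; for MIRI replicates 2 and 3 it was 15 and 10 of 27. A wrong label is argued against by the cytokine list, whose mean in sham replicate 3 was 1.52 against 1.66 in both other sham libraries and 3.76 to 4.10 in MIRI, and a liver source by liver markers at a mean of 0.389 FPKM, below the 0.515 of sham replicate 2. At which step kidney RNA may have entered stays open. No biological explanation was tested.

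The rise of cytokine and neutrophil genes could in part come from RNA of injured kidney, since 8 of 10 injury markers were at least 5 times higher in MIRI replicates 2 and 3 than in replicate 1. Against such RNA in MIRI replicates 2 and 3 as the whole source, the cytokine list mean of MIRI replicate 1 lay 2.09 above the highest sham library. The injury marker mean was 7.81 FPKM there against 2.04 in sham replicate 3, with Lcn2 at 50.8 against 3.30 (Lcn2 and Spp1 are also in the lists fixed for heart), while the other 8 markers had a mean of 0.284 against 0.293. Kidney RNA of the kind in sham replicate 3, scaled by the ratio of 6.68, gave at least 0.5 of the excess of MIRI replicate 1 for 0 of 29 called cytokine and neutrophil members (2 and 5 with sham replicates 1 and 2 in its place), but for 509 of all 1553 higher genes (322 and 619), where it does not separate kidney RNA from differences between sham libraries. Cytokine transcripts made in the kidney of MIRI replicate 1 itself, and a response of the heart to ischemia and reperfusion, both stay open and untested.

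The excess of lower genes, 66.9% of calls, may depend on the scaling of FPKM, since the share was 47.1% with median-ratio factors, 63.0% with quantile normalization and 70.0% with rescaling to TPM. Median-ratio factors bring the median change near 0 by construction, so their share does not show which scaling is right. The share of lower calls was also 50.7% with the kidney covariate, which left the scaling unchanged and gave fewer calls. The FPKM values hold no measure of total RNA per sample, so a scaling effect and a broad fall cannot be told apart.

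The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 1553 higher and 3142 lower genes and 298 list members, against at most 1, 1 and 0 in the other splits, so 1 of 10 splits reached each. Each of the other splits put sham and MIRI libraries together in both groups. Any difference between sham and MIRI then widens the spread within the groups, so few calls follow there. The gene counts of these splits are therefore no measure of what unrelated groups would give. For called lists 2 of 10 splits reached 19, the real one and that of sham replicate 1 with MIRI replicates 1 and 2. The other splits called 11 to 19 lists, so the number of lists called by camera at the preset correlation does not set the real split apart.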
